A study of Mus musculus with 50 samples.

How the data were processed

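Total RNA from the spinal cord and the testis of mice homozygous for the wobbler mutation (wr/wr) was compared with wild-type RNA of the same organ on 2-colour arrays, 50 arrays in all. Per the labels' protocols, RNA was purified on silica columns, 20 µg were reverse transcribed, and the cDNA was coupled indirectly to Cy3 or Cy5 before hybridisation. In the testis, each of 10 mutant mice was hybridised on 4 arrays against 1 pool of wild-type testis RNA. In the spinal cord, 3 mutant RNAs were hybridised against 1 pool of wild-type cord RNA: pool1 and pool2, each from 4 mutant mice, on 4 arrays apiece, and the cord of mouse 5995 on 2 arrays. All 9 mutant mice of the cord RNAs are among the 10 testis mice. On every RNA the dyes were swapped on an equal number of arrays, with the mutant RNA in Cy5 or in Cy3. The sample labels give 10 wild-type mice per reference pool and the labelling protocol gives 6, and this difference was not settled.

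The values used are the authors' deposited table of 1 log2 ratio per probe and array, and no scanner intensities were used here. The background correction, normalization and filters behind these log2 values are not given in the sources used here. The deposited log2 values were centred near 0 on each array, with medians from -0.027 to 0.032 in testis and from -0.091 to 0.058 in cord. Their median absolute deviation had a median over arrays of 0.259 in testis and 0.521 in cord. Between 19070 and 20189 probes had a value on a testis array, and between 18338 and 20034 on a cord array. A set of 1472 values (0.1485% of all, on 1189 probes) lay between 15.642 and 16.976 in size, with none between 10 and 15. Without intensities, they are read here as ratios with 1 channel at its floor, a reading that was not tested. They were kept, and treating them as missing is an alternative chosen after seeing the data.

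The direction of the ratios is not stated in the sources used here and was read from the values. The floored values were positive on all 586 occasions with the mutant RNA in Cy5 and negative on all 886 with it in Cy3, so that, with the ratio read as mutant over wild type on every array, that channel would always be Cy3. With the difference between the dye orientations taken per probe, testis and cord correlated at a Spearman rho of 0.263 across probes, against -0.163 for the mean of the orientations, as a dye effect that the 2 tissues share would give if every array had already been turned to 1 direction. No sign was therefore turned. The rule fixed beforehand would have turned an RNA when its Cy5 and Cy3 arrays correlated below 0, which they did in the cord (rho -0.228 for pool1, -0.0205 for pool2 and -0.0606 for mouse 5995) and in testis mice 5905 (-0.223), 6065 (-0.309) and 5997 (-0.112). It was not applied because an uncorrected dye effect also lowers this correlation. In testis, a further reason was that the arrays of some mice would then have run in opposite directions to the rest. That reason does not hold in cord, where the rule would have turned every RNA alike by dye. The cord results under the rule were not run. The reading as wr/wr over wild type is likely, from the order of the channels in the labels. The fixed check was the astrocyte and the microglia list in cord. By the list test described below, microglia were higher (median 0.60, adjusted p = 1.08e-12), while astrocytes did not pass (median 0.09, adjusted p = 0.0636). The direction of these lists is therefore not independent of the reading. With the opposite reading every sign below would turn.

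Each array was centred on its median. For each RNA, arrays of 1 dye were averaged, and the means of the Cy5 and Cy3 arrays were averaged again, so that a constant dye effect cancels and the arrays of 1 RNA count as 1 replicate. Before this averaging, arrays agreed more by dye than by RNA. In cord, the median Spearman rho was 0.239 for pairs of other RNAs in the same dye. It was -0.0795 for pairs of the same RNA in the other dye. In testis these medians were 0.196 and 0.109. Probes were tested with values in both dye orientations in at least 8 of 10 testis mice (20218 probes) or in all 3 cord RNAs (17055 probes). Mean ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Because 1 pool stands for the wild type of a tissue, this test leaves out the spread among wild-type mice. The tissue difference, the testis ratio minus the cord ratio, was fitted over the 13 RNAs with 1 pooled spread, on the 17005 probes tested in both tissues. The cord RNAs come from the same animals as the testis RNAs. Across probes, the deviations of each cord RNA and of the testes of its mice from their tissue means correlated at r = -0.00268 for pool1, 0.0157 for pool2 and 0.00483 for mouse 5995. The fit with each cord RNA paired with the testes of its own mice was planned as an alternative. It rests on 1 difference for each of the 3 cord RNAs, and its power was not simulated.

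Before the data were examined, 26 gene lists were fixed: cell types of the cord (astrocytes, microglia, motor neurons, other neurons, oligodendrocytes, nerve roots), cell types of the testis (Sertoli, Leydig and peritubular cells, spermatogonia, spermatocytes, round and elongating spermatids), off-tissue cells (skeletal muscle, red blood cells, endothelium), and pathways (complement and MHC class I, neuronal injury, cholesterol synthesis, the GARP complex, lysosome, ER stress, heat shock, respiratory chain, ribosomal proteins, and genes near Vps54). Lists with at least 5 measured genes, 25 in each tissue, were tested with cameraPR at a preset inter-gene correlation of 0.01, 2-sided, with 1 probe per gene. The nerve root list had too few measured genes. The calls were repeated with correlations estimated from the residuals and with fry.

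Genes were named by a rule fixed at the same time. Vps54 came first. Among called probes with 1 gene symbol and the same sign in every RNA, the 12 largest positive and the 12 largest negative ratios followed, then up to 4 members with the smallest p of each called list, and for the tissue difference 8 each way. Where fewer than 5 probes passed, the 5 probes with the smallest p each way were given as values. Cyp11a1, Star, Scarb1, Hsd3b1, Tekt4 and Ldhb in testis, and the epididymis and liver genes given further below, were named outside this rule. Other genes named outside it are said to be so where they appear. Of 20355 probes, 14030 had 1 gene symbol, 5 had several and 6320 were not listed with a gene; 13994 were matched by gene number to RefSeq (assembly GRCm38.p6), used only for names and gene order. The named probes stand for 9930 genes, of which 3004 have more than 1 probe. Probes of close relatives (the Hsd3b, H2, ribosomal protein and Cst families) may share targets, so their identities are uncertain.

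On simulated data based on the spread of each probe, 200 probes per tissue were shifted. Array noise was added to RNA deviations whose spread already held it, so the simulated RNAs varied more than the real ones. The shares recovered and the shares of false calls hold for these settings only. The testis fit recovered 76% of shifts of 0.5 and 90% of shifts of 1 on the log2 scale (20218 probes), and 12 of its 178 calls were false. The cord fit recovered 0% at both sizes (17055 probes). The pooled fit of the tissue difference made 771 calls of which 554 were false (17005 probes). A difference test with each tissue's own moderated spread was added after seeing the data. On the simulated data it made 3 calls, of which 2 were false, and recovered 0% of shifts of 0.5 and 0.541% of shifts of 1. With tissue weights 114 of 178 calls were false, and the cause of the false calls was not tested.

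Alternatives fixed beforehand covered centring, array scale, missing values, robust eBayes, arrays as replicates, each dye orientation alone, averaging the probes of a gene, leaving out each RNA, an exact sign-flip test, weights, a fit of both tissues together, and a minimum size. Leaving out testis mice 5905, 5997 and 6065 was added after seeing the data. The number of arrays and RNAs limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.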

Results

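Wobbler mice carry a recessive mutation in Vps54, a subunit of the GARP complex that tethers vesicles returning from endosomes to the Golgi. Homozygous (wr/wr) animals lose motor neurons, and the males form sperm without a normal acrosome. The series profiled RNA in the spinal cord and the testis of such mice to find transcripts whose level differs from the wild type. Ratios of wr/wr over wild type were measured for 10 individual testes (40 arrays) and for 3 spinal cord RNAs (10 arrays), of which pool1 and pool2 each hold 4 mice and the last is the cord of mouse 5995. Values are deposited log2 ratios, centred on each array's median, with the dye orientations averaged, and are given as the mean ± SD over RNAs. The reading as wr/wr over wild type is likely and not stated in the sources used here. The array held 0 named probes for Vps54, so the mutated gene itself was not checked.

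In the testis, transcripts of Leydig cells, the cells that make testosterone, were lower in the mutants. Hsd17b3, which makes testosterone from androstenedione, fell by 0.55 ± 0.11 (SD, n = 10; adjusted p = 4.72e-05), and Ptgds, a prostaglandin D2 synthase, was at -1.62 ± 0.49 (adjusted p = 0.000295). Gstm1, a glutathione transferase, fell by 0.60 ± 0.20 (adjusted p = 9e-04), Cyp17a1, the 17-alpha-hydroxylase of androgen synthesis, by 1.16 ± 0.67 (adjusted p = 0.0118), and all 4 were below 0 in 10 of 10 mice. Cyp11a1, which starts steroid synthesis from cholesterol, fell by 0.27 ± 0.24 and was lower in 9 of 10 mice. Star, the carrier of cholesterol into mitochondria, was at -0.09 ± 0.28 and Scarb1, a lipoprotein receptor, at -0.06 ± 0.10, neither of them called.

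Of the 15 measured Leydig members, 5 were called lower and 0 higher, and adjusted over the list alone 5 were lower and 1, Hsd3b1 (0.25 ± 0.28), was higher. The list was lower than the other genes (median -0.08, mean -0.29, camera adjusted p = 8.18e-07), with a median of -0.0202 with the mutant RNA in Cy5 and -0.158 in Cy3. It was the only list of the testis called with an estimated correlation as well (adjusted p = 0.000626).

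**Figure D1:**
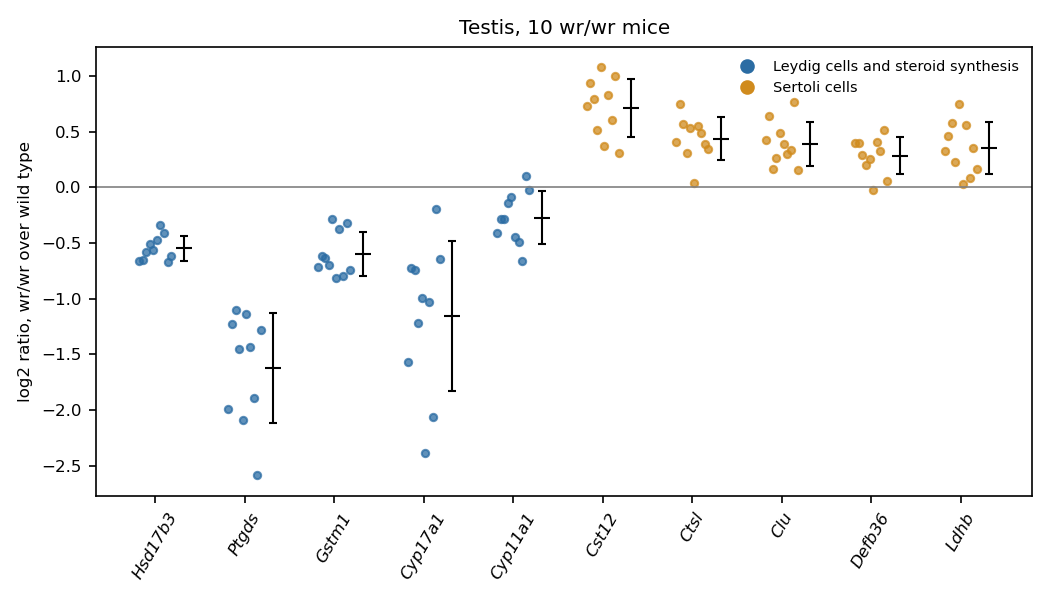
Log2 ratio of wr/wr over wild type in testis (vertical axis) for the 5 Leydig and the 5 Sertoli list members with the smallest p (horizontal axis). Points are 10 mice, and bars are the mean ± SD. All 10 values of Hsd17b3, Ptgds, Gstm1 and Cyp17a1 lie below 0, and all 10 values of Cst12, Ctsl, Clu and Ldhb lie above 0.

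Transcripts of Sertoli cells, which nurse the germ cells, were higher. Cst12, a cystatin of Sertoli cells, had the largest positive ratio among named genes, 0.72 ± 0.26 (1.64-fold, adjusted p = 0.00126). Ctsl, a secreted lysosomal protease, was at 0.44 ± 0.19 and Clu, the chaperone clusterin, at 0.39 ± 0.20, each higher in 10 of 10 mice, and Defb36, a beta-defensin, was at 0.28 ± 0.17. Of 17 measured Sertoli members 8 rose and 0 fell (8 and 1 adjusted over the list alone). The list passed the set test (median 0.21, camera adjusted p = 0.000165), but not with an estimated correlation (adjusted p = 0.0706).

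Transcripts of protein synthesis, folding and respiration rose together in the testis. Of 21 ribosomal protein transcripts 17 rose, with a median of 0.27, among them Rps14 (0.38 ± 0.22), Rpl32 (0.33 ± 0.19), Rpl27 (0.32 ± 0.19) and Rpl8 (0.29 ± 0.14). Of 26 respiratory chain transcripts all 26 were above 0 and 14 were called higher, 19 adjusted over the list alone, including Ndufb9 (0.32 ± 0.16) and Ndufv1 (0.30 ± 0.15) of complex I, Atp5b of the ATP synthase (0.30 ± 0.15) and Uqcrc1 of complex III (0.18 ± 0.05). Among ER stress genes 9 of 18 rose, 10 adjusted over the list alone, with the chaperones Hspa5 (0.29 ± 0.21) and Hsp90b1 (0.31 ± 0.23), the transcription factor Atf4 (0.26 ± 0.18) and the asparagine synthetase Asns (0.33 ± 0.25). Among heat shock chaperones 8 of 15 rose, 9 adjusted over the list alone, including the chaperonin subunits Cct4 (0.35 ± 0.18), whose gene is also on the list near Vps54, Tcp1 (0.25 ± 0.19) and Cct2 (0.23 ± 0.15) and the chaperone Hsp90aa1 (0.21 ± 0.14).

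These 4 lists passed the set test, with camera adjusted p = 3.26e-11 for ribosomal proteins, 5.06e-10 for the respiratory chain, 0.000194 for ER stress and 0.00173 for heat shock. None of them passed with an estimated correlation, where the adjusted p was 0.0713, 0.109, 0.109 and 0.0706 in the same order. Also in that order, their medians were 0.356, 0.286, 0.132 and 0.203 with the mutant RNA in Cy5. In Cy3 they were 0.201, 0.11, 0.202 and 0.105. Other probes of Atf4 (-0.07), Rpl32 (0.04) and Hsp90aa1 (-0.0015) lay near 0, whereas those of Rpl8 (0.245 and 0.252), Rps14 (0.372) and Tcp1 (0.206 and 0.221) were positive. Cct2 was at -0.02 (adjusted p = 0.863) when only arrays with the mutant RNA in Cy3 were used.

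Of the 4 germ cell lists only the meiotic one was called. Among 19 measured meiotic spermatocyte genes 4 rose and 1 fell (6 and 1 adjusted over the list alone). Ldhc, the lactate dehydrogenase of germ cells, was at 0.29 ± 0.14, Tdrd1 of the piRNA pathway at 0.28 ± 0.20 and the securin Pttg1 at 0.25 ± 0.17, while Rec8, a meiotic cohesin, fell by 0.28 ± 0.20. The meiotic list passed the set test (median 0.13, camera adjusted p = 0.00568) but not with an estimated correlation (adjusted p = 0.2). Its median was 0.208 with the mutant RNA in Cy5, positive in 10 of 10 mice, and 0.0224 in Cy3, positive in 7. Of the spermatogonial members 0 of 13 were called, of the round spermatid and acrosome members 0 of 30, and of the elongating spermatid members 6 of 37, all higher. Adjusted over the list alone the counts were 0, 0 and 7, with Tekt4 the lower one among the 7 (-0.15 ± 0.14). These 3 lists did not pass (adjusted p = 0.651, 0.65 and 0.123), but the elongating spermatid list did without mouse 5995 (median 0.08, adjusted p = 0.00583).

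Macrophage transcripts were slightly lower in testis. Cd68, a lysosomal glycoprotein of macrophages, fell by 0.37 ± 0.26, the complement components C1qa by 0.24 ± 0.19 and C1qc by 0.15 ± 0.08, and the lysozyme Lyz2 by 0.18 ± 0.13. Of 21 members 5 fell, and adjusted over the list alone 7 fell and 1 rose (median -0.09, camera adjusted p = 0.00657, and 0.0713 as adjusted p with an estimated correlation). Another Lyz2 probe was at 0.27, and the mean of the gene's probes was 0.05 (adjusted p = 0.673). The list named for motor neurons was lower too (3 of 8 members, median -0.11, camera adjusted p = 0.0246, and 0.0706 as adjusted p with an estimated correlation). Its called members were Mmp9, a matrix protease (-0.24 ± 0.12, with another probe at 0.13), Nefh, a neurofilament subunit (-0.19 ± 0.15), and Ache, acetylcholinesterase (-0.17 ± 0.14), while Ret was at -0.15 ± 0.24 (adjusted p = 0.199). Without mice 5905, 5997 and 6065, a setting chosen after seeing the data, this list had an adjusted p of 0.0669, and with the probes of a gene averaged 0.136.

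The other 16 lists tested in testis did not pass, with adjusted p from 0.104 for neurons and synapses to 0.969 for oligodendrocytes; they were those already given for germ cells and astrocytes, complement, neuronal injury, muscle, red blood cells, endothelium (-0.07), cholesterol synthesis, the GARP complex (0 of 14 members called), lysosome, genes near Vps54 (2 higher and 1 lower of 15) and peritubular cells (0 of 7). Median, mean and test differed in sign for neuronal injury (median 0.01, mean -0.17), myelin, red blood cells and cholesterol synthesis in testis, and for heat shock (median -0.15, mean 0.10), red blood cells, endothelium and spermatogonia in cord, none of them called there.

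Beyond the lists, the largest ratios in testis were negative. Srsf11, a splicing factor, fell by 1.99 ± 0.52 (adjusted p = 8.21e-05), Nhlrc2 by 1.65 ± 0.39 (adjusted p = 3.74e-05), the angiotensin precursor Agt by 1.41 ± 0.27 (adjusted p = 1.42e-05) and the siderophore-binding lipocalin Lcn2 by 1.39 ± 0.52 (adjusted p = 0.00126). Other probes of Nhlrc2 (0.01 and 0.07) and Lcn2 (-0.11) were not called. A further 6 of the 12 largest negative ratios belong to a set of 26 probes, among the 81 called probes of at least 0.5 in size, whose ratios followed those of Itih2 across the mice at r of 0.8 or more (795 of all testis probes reached that r): Atp5h (-1.48 ± 1.26), Nt5c (-1.37 ± 0.77), Itih2 itself (-1.28 ± 1.22), Glul (-1.25 ± 0.67), Hsf2bp (-1.14 ± 0.69) and Slc1a2 (-1.08 ± 0.78). Their medians ran from -2.50 in mouse 5907 to -0.23 in mouse 5905. In 11 genes of this set with further probes, those probes lay closer to 0, by 0.89 in the median.

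The positive ratios were smaller. After Cst12 came Tnnt3, a troponin of fast muscle (0.65 ± 0.54, n = 8), with another probe at -0.35, Hes1, a Notch target (0.58 ± 0.29), Tmsb4x, thymosin beta 4 (0.50 ± 0.29), S100a10 (0.50 ± 0.26), Tdrd5 of the piRNA pathway (0.48 ± 0.39), with another probe at -0.17, Synj2bp (0.47 ± 0.42), Ift122 of intraflagellar transport (0.45 ± 0.39, n = 9), Sec63 of the ER translocon (0.45 ± 0.26), the small nucleolar RNA Snord15b (0.41 ± 0.28) and the cystatin Cst13 (0.41 ± 0.26). Other probes of Ift122 (-0.04), Sec63 (0.03) and Snord15b (-0.03) lay near 0.

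In all, limma called 2494 of 20218 probes in testis (1640 genes), 1471 higher and 1023 lower, with a median size of 0.204. Only 81 had a size of 0.5 or more, 70 of them lower, and 6133 had an unadjusted p under 0.05 where 1011 would be expected if no probe differed. The count fell to 755 without mouse 6493, 1001 without 6069, 1237 without 6335, 1244 without 5907, 1495 without 5995 and 1554 without 5906; with only the Cy3 arrays it was 1352, with 38.3% higher in place of 59%. Of 753 genes with several probes and a call, 74 had every probe called and 14 had calls in both directions.

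**Figure D2:**
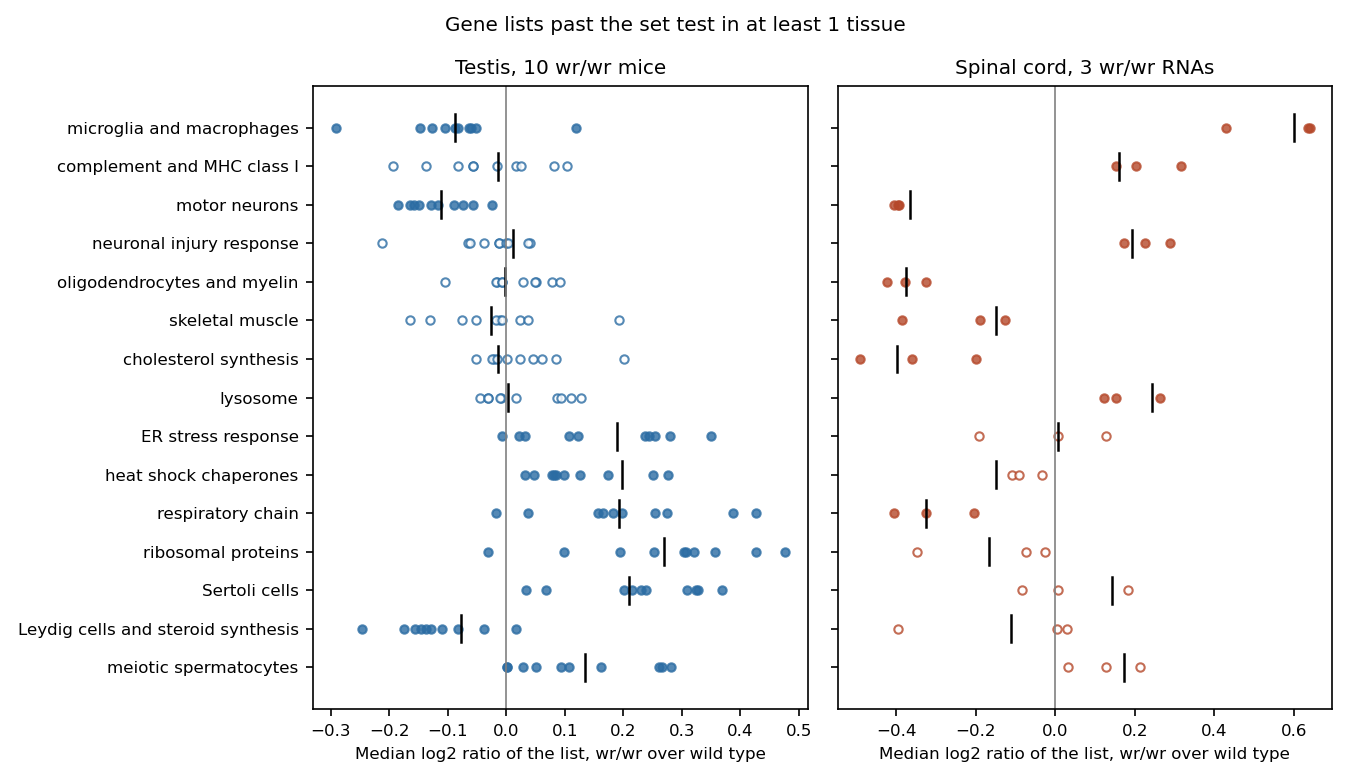
Median log2 ratio of wr/wr over wild type (horizontal axis) of each gene list called in at least 1 tissue (vertical axis), for 10 testis mice and 3 spinal cord RNAs. Filled points mark lists called in that tissue, open points lists that were not, and the black bar is the median of the genes' mean ratios. The microglia medians of the cord lie between 0.43 and 0.64, and its myelin medians between -0.42 and -0.33.

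In the spinal cord, the microglia list was higher and the myelin and motor neuron lists lower in the mutants, the last not without pool1 (adjusted p = 0.0787). Lgals3, a lectin of activated microglia, was at 1.43 ± 0.31 (SD, n = 3), Mpeg1, a macrophage perforin, at 0.86 ± 0.13, and C1qa at 0.67 ± 0.12, each positive in 3 of 3 RNAs. The myelin genes Mbp and Mobp were at -0.73 ± 0.25 and -0.72 ± 0.03, and the neurofilament subunits Nefh and Nefm at -0.90 ± 0.08 and -0.75 ± 0.14, each negative in 3 of 3 RNAs. No single probe passed the test across all probes, so these genes are given as values and the calls are those of the lists.

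**Figure D3:**
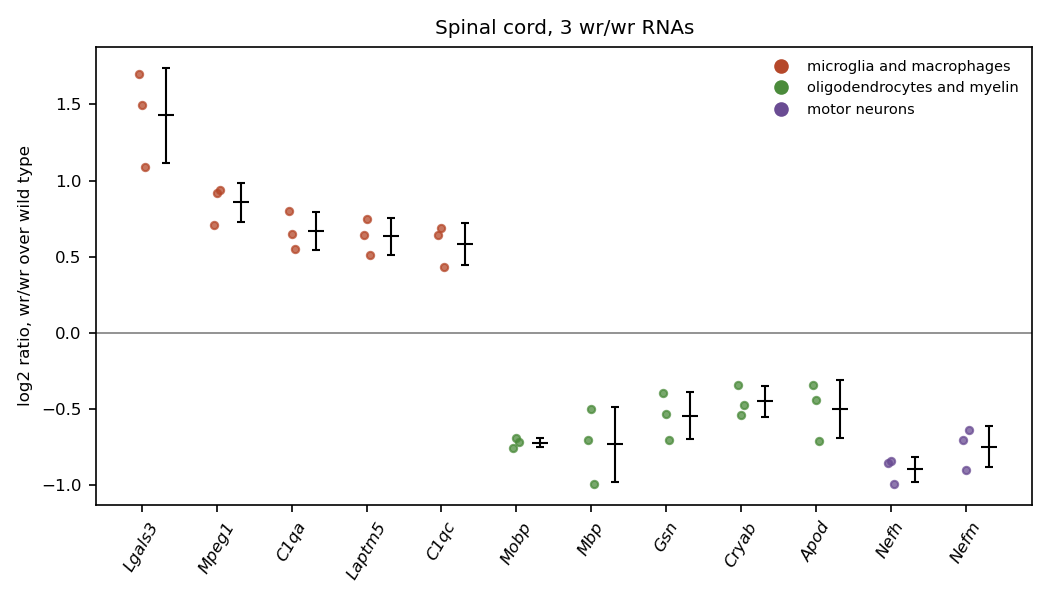
Log2 ratio of wr/wr over wild type in spinal cord (vertical axis) for 5 microglia, 5 myelin and 2 motor neuron list members chosen for small p (horizontal axis). Points are 3 RNAs (pool1, pool2 and mouse 5995), and bars are the mean ± SD. All values of the drawn microglia members lie above 0, and all others drawn below 0. In the full lists, 15 of 17 microglia, 2 of 14 myelin and 1 of 6 motor neuron members had a mean above 0.

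The microglia list had 17 measured members, of which 7 were higher adjusted over the list alone (median 0.60, camera adjusted p = 1.08e-12, and adjusted p = 1.08e-14 with an estimated correlation). Laptm5 (0.63 ± 0.12) was among them, as were C1qa and C1qc, which also stand on the complement list. Lysosomal transcripts were higher as a group (19 members, 0 passing singly, median 0.24, adjusted p = 0.000386), with Cd63 at 0.66 ± 0.06, the progranulin gene Grn at 0.49 ± 0.08, the cathepsin Ctsz at 0.48 ± 0.24 and the hexosaminidase Hexa at 0.35 ± 0.08. The complement and MHC class I list was higher (median 0.16, adjusted p = 0.0155), with C1qc at 0.59 ± 0.14, H2-K1 at 0.57 ± 0.29 and the immunoproteasome subunit Psmb8 at 0.57 ± 0.46, but not with an estimated correlation (adjusted p = 0.152). The neuronal injury list was higher (16 members, median 0.19, adjusted p = 0.0428), with the regeneration genes Sprr1a (1.09 ± 0.45), Atf3 (0.62 ± 0.30) and Ecel1 (0.70 ± 0.39), and with the small heat shock protein Cryab, which is also on the myelin list, at -0.45 ± 0.10. Apart from complement and muscle, the 7 other called lists were called with an estimated correlation too, with an adjusted p of at most 0.0335. For microglia, motor neurons, neuronal injury and lysosome the estimate from 3 RNAs was 0, below the preset 0.01. For these lists it was thus a looser test than the main one. With the mutant RNA in Cy3 the median of the neuronal injury list was -0.0023, against 0.30 in Cy5.

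Myelin transcripts were lower as a group, 7 of 14 adjusted over the list alone (median -0.37, adjusted p = 1.88e-08; -0.126 with the mutant RNA in Cy5, where 1 of 3 RNAs was positive, and -0.611 in Cy3), with the actin-severing Gsn at -0.55 ± 0.15. The motor neuron list was lower, 2 of 6 members adjusted over the list alone, Nefh and Nefm (median -0.37, adjusted p = 0.000386), while the intermediate filament Prph was at -0.48 ± 0.68 and Ache at -0.26 ± 0.26. The motor neuron median was -0.252 in Cy5, with 1 of 3 RNAs positive, and -0.815 in Cy3. Respiratory chain transcripts were lower as a group (23 members, median -0.33, adjusted p = 2.09e-08; -0.0987 with the mutant RNA in Cy5, where 1 of 3 RNAs was positive, and -0.487 in Cy3), with Ndufa5 (-0.58 ± 0.23), Cox7c (-0.59 ± 0.36), the succinate dehydrogenase subunit Sdhd (-0.40 ± 0.08) and Uqcrc2 (-0.38 ± 0.15). Cholesterol synthesis transcripts were lower (12 members, median -0.40, adjusted p = 5.25e-05), with the HMG-CoA synthase Hmgcs1 at -0.57 ± 0.02, Pmvk at -0.78 ± 0.50, Fdps at -0.53 ± 0.24 and Ebp at -0.44 ± 0.06. The skeletal muscle list, an off-tissue check, was lower (10 members, median -0.15, adjusted p = 0.0219) and not called with an estimated correlation (adjusted p = 0.0888), with a median of -0.0033 in Cy5 and -0.333 in Cy3; its leading members were the glycogen phosphorylase Pygm (-0.75 ± 0.16) and myoglobin, Mb (-0.58 ± 0.09), followed by Pvalb (-0.20 ± 0.08) and Casq1 (-0.22 ± 0.22).

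Astrocyte transcripts were divided. The list did not pass (21 members, median 0.09, adjusted p = 0.0636), although both probes of the filament protein Vim, at 1.43 ± 0.20 and 1.15 ± 0.18, were among the 5 positive ratios with the smallest p. Gfap was at 0.69 ± 0.28 and S100b at -0.57 ± 0.07, both named outside the rule. With the probes of a gene averaged the list passed (adjusted p = 0.00152). The other lists not called were endothelium (median -0.12, adjusted p = 0.925), red blood cells (0.54), other neurons (0.143), ribosomal proteins (0.107), heat shock (0.434), ER stress (0.8), the GARP complex (0.434), genes near Vps54 (0.269), and the testis cell types, from 0.0626 for round spermatids to 0.835 for Leydig cells, each p adjusted over the lists. Of these, the meiotic and the round spermatid list passed without pool1 (adjusted p = 1.14e-06 and 0.0276), and the astrocyte list passed without pool2 (adjusted p = 0.0376).

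Besides Vim, the smallest p among positive ratios belonged to Itih2 (2.24 ± 0.53), the mitochondrial ribosome gene Mrpl53 (0.97 ± 0.08) and probe 13566 (1.16 ± 0.13), which has no gene here. Among negative ratios they were Cdkn1a, the cell cycle inhibitor p21 (-1.48 ± 0.32), Nefh, the glycerol phosphate dehydrogenase Gpd1 (-0.97 ± 0.21), and probes 10754 (-1.29 ± 0.31) and 11422 (-1.27 ± 0.33). limma called 0 of 17055 cord probes (smallest adjusted p = 0.542), and 1476 had an unadjusted p under 0.05 where 853 would be expected if no probe differed. On simulated data, which varied more among RNAs than the real data and held 200 shifted probes, this fit recovered 0% of changes of 1 on the log2 scale. The count of 0 is therefore not read as a limit on change. Without pool1 the adjusted p was 0.0787 for motor neurons, 0.175 for neuronal injury and for muscle, and 0.408 for complement; muscle was at 0.11 without mouse 5995 and complement at 0.0539 without pool2. By fry, which tests whether a list's genes move on balance one way, only the microglia list passed (adjusted p = 0.0198), with myelin at 0.0643 and motor neurons at 0.0516.

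Of 25 lists, 7 differed between the tissues and the other 18 did not pass (adjusted p from 0.0551 for astrocytes to 0.97 for meiotic spermatocytes). The difference, testis minus cord, was negative for microglia and macrophage transcripts (median -0.77, camera adjusted p = 1.26e-11) and for complement and MHC class I (-0.18, adjusted p = 0.0201). It was positive for the respiratory chain (0.52, adjusted p = 1.67e-12), ribosomal proteins (0.41, adjusted p = 0.000137), cholesterol synthesis (0.43, adjusted p = 0.000233), myelin (0.38, adjusted p = 0.00461) and heat shock chaperones (0.38, adjusted p = 0.0201). With each tissue's own spread, a test added after seeing the data, all 7 lists passed, with adjusted p from 1.28e-13 for the respiratory chain to 0.0333 for complement. Skeletal muscle and lysosome, not among the 7, passed there too (adjusted p = 0.0455 each). With cord RNAs paired with the testes of the same mice, complement did not pass (adjusted p = 0.108). With an estimated correlation, ribosomal proteins (adjusted p = 0.272) and heat shock (adjusted p = 0.0895) did not. Astrocytes, not among the 7, passed with an estimated correlation (adjusted p = 0.0389). Without pool1, complement was at 0.173, and heat shock was at 0.0803 without pool2 and at 0.0793 without the cord of mouse 5995.

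Among single genes, Itih2 was at -1.28 ± 1.22 in testis (n = 10) and 2.24 ± 0.53 in cord (n = 3), a difference of -3.52 (adjusted p = 0.00529, and 0.00422 with each tissue's own spread). Atp5h differed by -3.02 and Glul by -2.48, both also called with each tissue's own spread (adjusted p = 0.0106 and 0.0103), and Ap5z1, a subunit of an endosomal adaptor, by -2.98 (0.187 as adjusted p with its own spread). All 4 probes belong to the set that follows Itih2 in testis, and other probes of Atp5h (0.60) and Glul (0.12) did not share the difference. Cdkn1a differed by 1.40, from -0.08 ± 0.39 in testis and -1.48 ± 0.32 in cord (adjusted p = 0.00287, and 0.09 with its own spread). In the fit that paired cord RNAs with the testes of the same mice none of these 5 genes was called (adjusted p = 0.392 each), with unchanged signs.

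**Figure D4:**
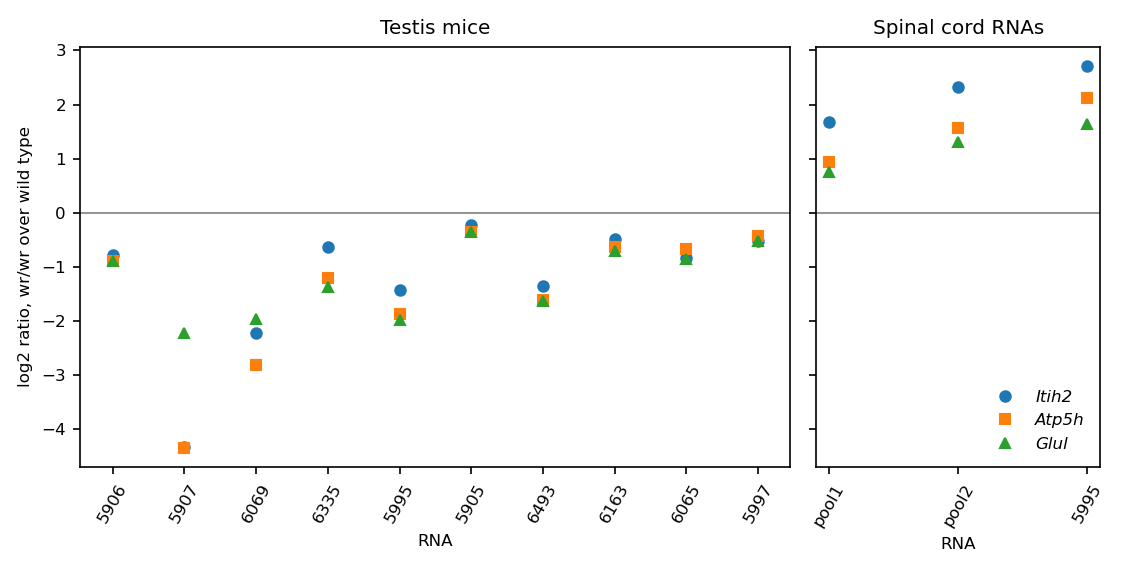
Log2 ratio of wr/wr over wild type (vertical axis) for the probes of Itih2, Atp5h and Glul in 10 testis mice and 3 spinal cord RNAs (horizontal axis). Each point is 1 RNA. All 3 probes lie below 0 in every testis, lowest in mouse 5907, and above 0 in every cord RNA.

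The other 11 named genes had cord SDs from 1.16 to 4.60, and 9 of their probes held values read as having a channel at its floor. Coro1a (3.97, with 2 such arrays), Gemin4 (3.60, 1 array), Slu7 (3.36, 1 array) and Cd320 (-3.60, 1 array) could not be tested without those arrays, and their cord SDs were 3.13, 4.60, 4.13 and 4.29. Without floored values Pqbp1 went from 2.20 to 0.81 (adjusted p = 0.193), Naa25 from 1.5 to 0.13 (adjusted p = 0.632), Vnn3 from -3.00 to -1.51, Tsr1 from -2.60 to -0.96 and Ano1 from -2.27 to -0.96. Anln (1.77) and Ccdc93 (1.57) held no floored value and had cord SDs of 1.93 and 1.73. With each tissue's own spread the adjusted p of these 11 genes ran from 0.231 to 0.405, but that test recovered only 0.541% of simulated differences of 1 on the log2 scale.

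The pooled fit called 3604 of 17005 probes as different between the tissues, 1836 with the higher ratio in testis, and 6254 had an unadjusted p under 0.05 where 850 would be expected if no probe differed. In simulated data with 200 shifted probes per tissue, 554 of 771 such calls were false. That share does not carry over to the real count. It is far more than the threshold of 0.05 on the adjusted p allows, so the count is not taken as reliable. With each tissue's own spread 21 probes passed, all with the lower ratio in testis. Of these 21, 14 belong to the set of 26 probes that follows Itih2 in testis. In simulated data that test made 3 calls, 2 of them false, and recovered 0.541% of differences of 1, so it does not replace the count. In the fit that paired cord and testes of the same mice 0 passed. That fit rests on 1 difference for each of the 3 cord RNAs, and its power was not simulated.

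Across the 17005 probes tested in both tissues, the mean ratios of testis and cord ran weakly against each other. Pearson's r was -0.122 and Spearman's rho -0.205, and 41.5% of probes had the same sign; genes are not independent replicates, so this is a description. Among the 2303 probes called in testis r was -0.384. The direction depended on the dyes: with only Cy5 arrays of the mutant RNA r was 0.0712 and with only Cy3 arrays 0.0182, whereas with opposite dyes in the 2 tissues it was -0.145 and -0.0999. With 0 cord probes called, an overlap could be counted only in a fit of both tissues together, in which 836 of 967 simulated cord calls were false. There 27 probes were higher in both tissues and 25 lower in both, where independent lists would share 72.86 and 38.04, and 93 were higher in cord and lower in testis and 138 the other way, where they would share 41.23 and 67.22.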

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

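The tests of a shared sequence among the probes that follow Itih2, of all Leydig list members falling alike, of the balanced myelin medians, and of microglia against endothelium were chosen only after the result was seen, as was the test with each tissue's own spread.

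Other arrangements of the samples were tried first. Of 100 drawn sign patterns over the 10 testis mice, out of 512 possible, 1, the real one, gave as many calls; the real count was 2494 and the highest of the others 831, so chance in the mice's own signs can be excluded for the testis count; a chance deviation of the single wild-type pool, which enters all 10 ratios alike, is not covered. Of 100 drawn splits of the 13 RNAs into 3 and 10, out of 286 possible, 1, the real one, gave as many; the real count was 3604 and the highest of the others 327. Chance cannot be judged from these splits, since in simulated data the pooled fit at the real grouping made 554 false calls of 771, more than the highest of the others. The splits also take the RNAs as exchangeable, although the cord RNAs come from the mice of the testes. The fit that pairs them called 0 probes, but it rests on 1 difference for each of the 3 cord RNAs.

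A first pattern is the set of 26 probes that follow Itih2 at r of 0.8 or more among the 81 called probes of at least 0.5 in size; among all testis probes 795 reach that r. Their median was below 0 in each testis mouse, from -2.50 to -0.23, and 24 of 26 were positive in cord, with medians of 0.44 in pool1, 0.79 in pool2 and 1.27 in mouse 5995. A dye effect left in the mean is argued against, since the median of the set was -0.925 in the orientation nearer to 0. In 11 genes of the set with further probes, those probes lay closer to 0 by 0.89 in the median, but in 18 other called probes of at least 0.5 in size the distance was 0.57, and the share of the ratio that further probes kept did not differ past the threshold (permutation p = 0.237). Whether 1 shared sequence or transcript lies behind the set, or the mutation or the strain background, therefore stays open, since probe sequences were not used here.

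A second pattern is the fall of Leydig transcripts in testis. A lower share of Leydig cells with all their transcripts falling alike is argued against. The means of all 15 members had an SD of 0.505, above the 0.342 reached at most with member labels permuted within each mouse (permutation p = 1e-04, the smallest that 10000 resamples give). Of the members, 9 lay above their mean of -0.285 and 4 below it by more than 2 SE. This concerns equal ratios of all members only, and a lower share of Leydig cells as such is not argued against. Epididymis in the wild-type pool is argued against by a list of 50 epididymis genes, 18 measured, of which 2 are on other lists (median 0.0872, SE of the mouse medians 0.0585, camera p = 0.102), with Lcn5 at -0.04 (SE 0.045) and Gpx5, too variable to count, at 0.31 (SE 0.311). Liver in the wild-type pool, as Agt and Apoc1 might hint, is argued against by a list of 50 liver genes, 29 measured, of which 1 is on another list (median -0.0575, SE 0.0185, p = 0.056; Fbp1 called higher, and Tat, Orm1 and Cfb lower at -0.24, -0.20 and -0.20), with Apoa1 at -0.07 (SE 0.0457) and Alb, too variable to count, at 0.475 (SE 0.467). The mutation, fewer Leydig cells with transcripts shared by other cells falling less, a difference in age or hormone state, and wild-type mice that happened to be high stay open, since 1 wild-type pool was used.

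The last pattern is the rise of microglia and the fall of myelin transcripts in cord. The microglia and endothelium lists did not rise alike. The microglia median exceeded the endothelium median by at least 0.585 in each of 3 RNAs (mean 0.638, SD 0.0461). This comparison was chosen after both medians were seen, and it rests on 1 list of 9 measured endothelium genes. A passive rise of all other cells when neurons and myelin fall therefore stays open beyond these 2 lists. A dye effect left in the mean is argued against for microglia, whose median was 0.566 with the mutant RNA in Cy5 and 0.506 in Cy3, positive in 3 of 3 RNAs each. For myelin, the median was -0.126 in Cy5, with 1 of 3 RNAs positive, and -0.611 in Cy3. A dye effect common to the arrays of an orientation cancels in the mean by construction. The balanced medians of -0.326, -0.379 and -0.424 (mean -0.376, SD 0.0492) are the fall itself, so they are no separate test. A dye effect that differs among arrays stays open for myelin. A reaction of microglia to the loss of motor neurons in the mutants is a hypothesis that these 3 RNAs may be consistent with but do not test, and wild-type spread, age and dissection stay open.

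Values of 1 mouse stood apart from the others in 6 of 81 groups of testis values (n = 10 in 79 of them, 8 for Tnnt3 and 9 for Ift122), where 4 would be expected by chance alone at 1 in 20 groups. The figure after each is the gap to the nearest mouse over the whole range, and all exceed Dixon's 95% critical value. The neuronal injury list was lowest in mouse 5907 (median -0.21, gap 0.583), and so was Itih2 (-4.33, gap 0.514). The elongating spermatid list was lowest in mouse 5995 (median -0.30, gap 0.47), where S100a10 was highest (1.11, gap 0.488). Synj2bp was highest in mouse 6163 (1.51, gap 0.567), and Ret was lowest in mouse 6065 (-0.69, gap 0.5).

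Differences between the tissues in the pooled fit, testis minus cord, were positive for Coro1a (3.97), Gemin4 (3.6), Slu7 (3.36), Pqbp1 (2.2), Anln (1.77), Ccdc93 (1.57), Naa25 (1.5) and Cdkn1a (1.4). They were negative for Cd320 (-3.6), Itih2 (-3.52), Atp5h (-3.02), Vnn3 (-3), Ap5z1 (-2.98), Tsr1 (-2.6), Glul (-2.48) and Ano1 (-2.27). Of these 16, Itih2, Atp5h and Glul passed with each tissue's own spread, a test that recovered 0.541% of simulated shifts of 1. The gene lists that differed had medians of -0.768 for microglia and macrophages, -0.18 for complement and MHC class I, 0.375 for myelin, 0.425 for cholesterol synthesis, 0.379 for heat shock chaperones, 0.521 for the respiratory chain and 0.408 for ribosomal proteins.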

How the results depend on the processing

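Treating floored values as missing, leaving out mice 5905, 5997 and 6065, each tissue's own spread in the difference, and the lists in a fit of both tissues were chosen only after the data were seen. The testis count of 2494 ran from 2476 to 3406 without centring, with arrays scaled, with floored values as missing, with either filter on missing values, with robust eBayes, with only Cy5 arrays, by the exact sign-flip test (2595) and without those 3 mice (2702). It moved to 1352 with only Cy3 arrays, 1273 with the probes of a gene averaged (fewer tests), 4450 with arrays as replicates and the RNA as a random block, 5158 with arrays as independent replicates, 1378 in a fit of both tissues, and 81 with a minimum size of 0.5. A similar count did not always mean the same probes. Of the 2494 probes, 1589 were also called with only Cy5 arrays and 743 with only Cy3 arrays. Leaving out 1 mouse gave 755 (without 6493) to 2584 (without 5905).

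The cord count of 0 became 251 with the RNA as a random block, 104 with independent arrays and 2707 in a fit of both tissues; in simulated cord data 13 of 58 calls of the random block and 836 of 967 of the joint fit were false. Under the other cord settings, leave-outs included, it was 0. The difference count of 3604 moved to 1256 with arrays scaled, 1604 with only Cy5 arrays, 1666 with probes averaged, 21 with each tissue's own spread, and 0 in the replicate block fit that paired each cord RNA with the testes of its mice; without 1 RNA it ran from 2754 (without cord 5995) to 4678 (without pool1). In the paired fit complement and MHC class I was the only one of the 7 differing lists not called.

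The correlation between tissues, -0.122, was -0.384 among called probes and -0.203 with floored values as missing, and turned to 0.0712 with only Cy5 and 0.0182 with only Cy3 arrays. Of 9 testis lists 1 was called with an estimated correlation; of 9 cord lists 1 was called by fry. Leaving out 1 RNA gave 9 to 10 lists in testis and 7 to 9 in cord, where 4 of the 9 were not called without pool1. Averaging probes called the astrocyte list in testis (median -0.06, adjusted p = 0.00507) and in cord (0.18, adjusted p = 0.00152). Of the named genes, Lyz2 in testis turned to 0.045 with probes averaged and Cct2 to -0.0245 with only Cy3 arrays, neither called. Of 55 named testis calls 24 were lost with only Cy3 arrays, 19 without mouse 6493, and at most 10 in any other setting; of 16 named differences 16 were lost in the paired fit and 13 with each tissue's own spread. Of the settings of named cord values, of which 0 were called, 610 left them uncalled and 70 called them. Turning every sign was not run separately, because it reverses each direction by construction. Turning the cord RNAs by dye, as the rule fixed beforehand would have done, is a different step and was not run. Where no construction or simulation is named, the cause was not tested. Signal over background is unknown without intensities, and the number of RNAs, 3 in cord, limits precision.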

Other observations

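The test of ribosomal against respiratory transcripts across mice, and the choice of the genes in the first paragraph, came only after the result was seen.

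The 20 testis probes with the smallest p were all lower, in 10 of 10 mice each. Some of the genes are on none of the fixed lists, and no common function was tested. Ephx1, an epoxide hydrolase, fell by 0.90 ± 0.17 (SD, n = 10; limma adjusted p = 1.42e-05), Ugt1a6a, a glucuronosyltransferase, by 0.72 ± 0.19 (adjusted p = 0.000146) and Apoc1, an apolipoprotein, by 0.56 ± 0.09 (adjusted p = 1.42e-05). The steroid dehydrogenase genes Hsd3b2 and Hsd3b3 fell by 0.68 ± 0.12 and 0.74 ± 0.16, whereas the probe of Hsd3b1, a close relative, was at 0.25 ± 0.28 (adjusted p = 0.0665). Ass1 of arginine synthesis fell by 0.65 ± 0.19, Spon1, a matrix protein, by 0.73 ± 0.24, the selenium carrier Selenop by 0.32 ± 0.07 and the ubiquitin ligase Rnf41 by 0.44 ± 0.10. Further probes of Ass1 (-0.25 and -0.02), Spon1 (-0.11 and 0.15) and Hsd3b3 (-0.48) lay closer to 0, and a further probe of Rnf41 was at 0.07.

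A hypothesis was that genes flanking Vps54 differ more often, as variants carried along with the mutation may give. Among the 200 protein-coding genes nearest to Vps54 on its chromosome, 100 on each side in GRCm38.p6 order, 119 were measured, and 24 of their 160 probes (15%) were called in testis, against 1756 of 13757 other named probes (12.8%). The odds ratio was 1.21 (95% interval 0.745 to 1.88, Fisher's exact p = 0.404), an interval too wide to decide.

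A second hypothesis was that lists rising in testis vary together among mice. The respiratory chain median followed the ribosomal protein median over 10 mice (Pearson r = 0.934, permutation p = 0.00015; Spearman rho = 0.867, permutation p = 0.0021; adjusted p = 0.00075 over 5 relations). Without mice 5997 and 5905, the farthest from the median, r was 0.857, so 1 common factor among mice, of biology or of RNA handling, may lie behind both lists. The Sertoli median also followed (r = 0.84, rho = 0.685, permutation p = 0.0026 and 0.035; adjusted p = 0.0065), but r was 0.543 without those 2 mice. Leydig (r = -0.11, rho = -0.0182, permutation p = 0.76 and 0.97) and elongating spermatid medians (r = 0.00865, rho = 0.321, permutation p = 0.98 and 0.37) did not follow. The relation of the ribosomal median to how well a mouse's dye orientations correlate (r = 0.618, rho = 0.624, permutation p = 0.055 and 0.061, adjusted p = 0.092, and r = 0.386 without those 2 mice) leaves open whether array quality sets part of it. Labels give no batch for these arrays, so no value within batches could be had.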
